A study of Mus musculus with 12 samples.

How the data were processed

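The data were microarray measurements of RNA from mouse embryonic stem cells, the self-renewing cells of the early embryo. Both alleles of Thap11, the gene that encodes the zinc finger protein Ronin, were flanked by loxP sites in all cells. The knockout cells also carried CreERT2, a Cre recombinase that tamoxifen brings into the nucleus, where it cuts out the flanked part of the gene. The control cells had the same flanked alleles and no CreERT2. Per the labels' protocols, 100000 cells were plated per 10 cm2, both kinds of cells received tamoxifen at 0.25 uM, and cultures were split on day 4. Collection was on days 1.5, 3 and 6 of the treatment. Each of the 6 groups had 2 arrays, 12 in all. CreERT2 was present in every knockout sample and in no control sample, so its own effect and any difference between the lines cannot be separated from the loss of Thap11.

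The arrays were of the Affymetrix Mouse Genome 430 2.0 design. The deposited values are intensities per probe set made with RMA, per the submitters' processing notes, which name no version. RMA corrects background, puts all arrays on a common distribution and summarises the probes of a probe set. The values ran from 5.511 to 34993, a linear scale, whereas the design fixed beforehand had assumed log2 values. The log2 of each intensity was therefore taken before any test. Array medians ran from 42.37 to 44.72, with all arrays of day 3 at 44.36 to 44.72 and the others at 42.37 to 43.04. The number of arrays limits the precision, and no detection calls, scan dates or batches were used here.

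Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none. Symbols were compared with a RefSeq gene table of the GRCm38.p6 assembly, where 34754 probe sets matched by gene ID and 0 symbols needed an update. That table served for names and for which genes neighbour each other, since the sources used here give no genome build for the probe sets. For each gene the brightest probe set over all arrays was tested, which gave 18194 genes, with no filter on dim genes. Where other probe sets of a named gene moved the other way past the threshold, or where the probe set's suffix marks probes shared with other transcripts, the text says so.

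Groups were compared with limma 3.58.1 in R 4.3.3, with a mean per group over all 12 arrays and eBayes moderation (6 residual and 3.04 prior degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so p-values measure the spread between these arrays only, which may be technical. The comparisons were knockout against control on each day, the differences of that effect between days, and controls of days 3 and 6 against day 1.5. Knockout comparisons of different days share no arrays. The test of 27 gene lists, fixed before the data were examined, was camera with a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. The second run also rests on the 6 residual degrees of freedom, whereas the first takes them from the number of genes. For extraembryonic endoderm genes of day 1.5 the estimated correlation was 0.0068, below the preset. Their unadjusted camera p still went from 4.5e-09 to 0.00095. A call lost in the second run therefore does not measure the correlation alone. Lists with fewer than 5 measured genes would have been left out. Older names were matched through synonyms, by which Gpi1 of the glycolysis and hypoxia list became Pigq, and the name pattern of the translation initiation factors took in 7 kinases and binding proteins. Both lists were also tested without these, an alternative chosen after seeing the data. Plots were drawn with matplotlib 3.10.9.

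The rule for named genes was also set before the data were examined. On each day it takes the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold whose knockout and control arrays do not overlap, leaving out symbols that are only clone or model numbers. It adds up to 4 members past the threshold and the 2 brightest others from each list, 5 genes per direction for changes between days and for the control time course, and always Thap11, Hcfc1, Pou5f1, Nanog, Sox2, Cdkn1a and Mmachc. Alternatives were a term for the replicate number (over all arrays, or within a day), only the arrays compared, another eBayes setting, array weights, leaving out the dimmest 40% of genes, the mean of all probe sets of a gene, median centring, quantile normalization and leaving out each array. The gene-level test was run on simulated data with the real gene means and residual spreads, drawn independently for each gene. Among 18194 genes, 200 were changed and the genes of a further list were shifted. For knockout against control on day 6 the test recovered 28.1% of genes changed 1.25-fold, 68.7% of those changed 1.5-fold and 93.3% of those changed 2-fold. Of its calls there, 5.34% were false. The share of false calls was 7.35% on day 1.5, 4.82% on day 3 and 5.83% for controls of day 6. For the difference between days 6 and 1.5 the shares recovered were 6.27%, 46.9% and 79.4%, with 5.58% of calls false. The real knockout comparisons called far more genes, 1803, 4250 and 5906 on days 1.5, 3 and 6. With more calls the adjustment sets another cutoff, so the simulated shares do not carry over to those comparisons.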

Results

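RNA was measured in 12 samples of mouse embryonic stem cells in which Thap11, the gene for the transcription factor Ronin, could be deleted. Control and knockout cells were collected after 1.5, 3 and 6 days of tamoxifen, with 2 arrays per group. Over 18194 genes the log2 intensities of the 2 arrays of a group correlated with r between 0.99816 and 0.99856, and the SD of their log2 difference lay between 0.145 and 0.162. The first principal component held 45.2% of the variance and ran from the controls of day 3 to the knockout cells of day 6. The second held 20.2% and set both genotypes of day 3 apart from the other controls.

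**Figure D1:**
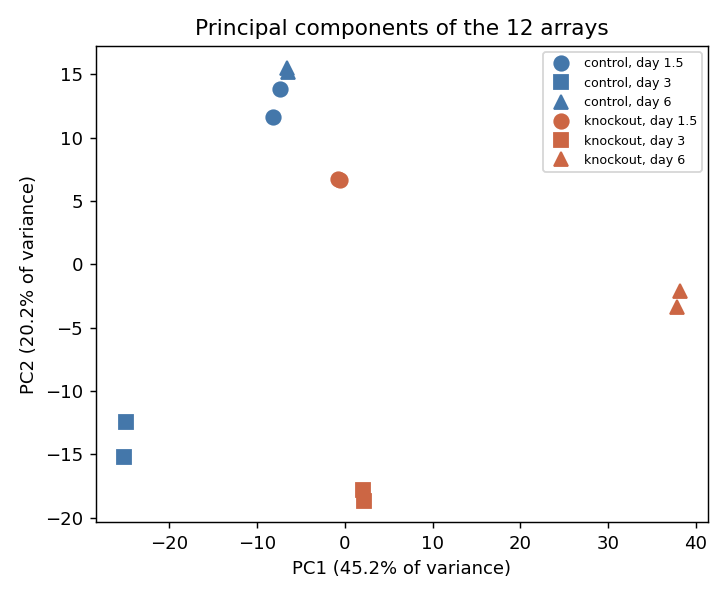
First (x axis) and second (y axis) principal components of log2 intensity over 18194 genes, 1 point per array, coloured by genotype and shaped by day. The 2 arrays of each group lie together, controls of day 3 sit at the lowest values of the first component and knockout cells of day 6 at the highest.

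The first comparison checks the deletion itself. Thap11 was read by 1 probe set. Its intensity in controls was 1222 ± 56.9 on day 1.5, 1284 ± 8.13 on day 3 and 1344 ± 54.0 on day 6 (mean ± SD, n = 2 each). In knockout cells it was 340.8 ± 18.9, 101.4 ± 12.3 and 51.07 ± 0.605 on the same days, or 27.9%, 7.9% and 3.8% of control. The log2 fold changes were -1.84, -3.67 and -4.72 with a standard error of 0.083 on each day (limma adjusted p of 1.2e-05, 1.4e-07 and 1.4e-08). Whether this probe set lies inside the deleted part of the gene was not analysed here. Mmachc, which encodes a protein that processes vitamin B12, fell on every day, by 0.54, 1.71 and 3.66 on the log2 scale. Its intensity on day 6 was 601.9 ± 4.86 in controls and 47.61 ± 4.92 in knockout cells (SD, n = 2).

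**Figure D2:**
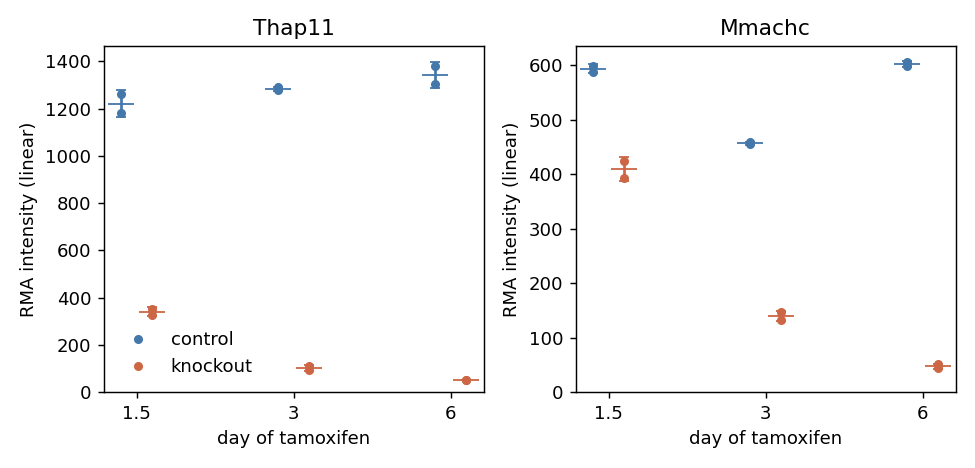
RMA intensity (linear, y axis) of Thap11 and Mmachc by day of tamoxifen (x axis), with a point per array and the mean ± SD of 2 arrays. In knockout cells Thap11 went from 340.8 on day 1.5 to 51.07 on day 6 and Mmachc from 408.5 to 47.61, while the lowest control array read 1181 for Thap11 and 454.8 for Mmachc.

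On day 1.5 the largest rise was in Ubd, a ubiquitin-like modifier, with an intensity of 24.45 ± 1.61 in controls and 282.3 ± 16.7 in knockout cells (SD, n = 2, log2 fold change 3.53 ± 0.20 SE). Galc, a lysosomal enzyme that breaks down galactolipids, rose by 2.58 ± 0.21 and the transcript of the Rosa26 locus, Gt(ROSA)26Sor, rose by 2.18 ± 0.10. Caps2, Mrc1, Prex2, Fxyd6 and St8sia1 followed, with log2 fold changes from 1.50 to 1.96. The largest falls were in Ccnb1ip1, at -2.40 ± 0.054, Tesc, at -1.88 ± 0.069, Thap11 itself and the smooth muscle actin gene Acta2, at -1.61 ± 0.11. Xaf1, Zfp607b, Gbp2 and the immediate early gene Fos also fell, by 1.58, 1.44, 1.40 and 1.33. The second probe set of Xaf1 moved the other way past the threshold, and its mean over both probe sets was 0.013, so its direction is unsettled. The probe sets of Tesc, Acta2 and Gbp2 share probes with other transcripts. Galc, Caps2 and Prex2 had other probe sets, none of which passed.

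In all, 1803 of 18194 genes passed on day 1.5, 1079 higher and 724 lower, of which 19 rose and 30 fell at least 2-fold. The count was 833 without control replicate 1, 792 without control replicate 2, 750 without knockout replicate 1 and 714 without knockout replicate 2 of that day, and 455 when only the 4 arrays of day 1.5 entered the test. Of 27 gene lists, 3 shifted, each downward, and 5 without control replicate 1 of day 1.5. Among extraembryonic endoderm genes, 8 of 20 fell and 0 rose (10 and 0 adjusted over the list alone), with Gata6 at -0.91 ± 0.12, the collagen gene Col4a1 at -0.78 ± 0.085 and Sox7 at -0.72 ± 0.084. Their list median was -0.33 (camera adjusted p = 1.2e-07, and adjusted p = 0.026 with an estimated correlation). Among primed epiblast genes 5 of 13 fell (5 adjusted over the list alone), including Otx2, at -0.84, Fgf5, at -0.84, and Pou3f1, at -0.83 (adjusted p = 0.0028, and adjusted p = 0.23 with an estimated correlation). Markers of fibroblasts or feeder cells had 6 of 23 members lower and 0 higher (7 and 1 adjusted over the list alone), among them Tagln, at -0.96 ± 0.064, and Cav1, at -0.70 ± 0.082. That list had an adjusted p of 0.006, and an adjusted p = 0.39 with an estimated correlation. Germline genes had 0 of 14 members past the threshold.

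On day 3 the largest rises were in Pramel6 and Pramel7, of the PRAME-like family, at 3.08 ± 0.097 and 2.17 ± 0.088 on the log2 scale, and in Sycp1, a part of the meiotic synaptonemal complex, at 2.34 ± 0.12. Galc remained higher at 2.13 ± 0.21, and Trmt10a, a tRNA methyltransferase, rose by 2.00 ± 0.057. Egfl6, Myof and Anxa1 rose by 1.93, 1.87 and 1.84. Below Thap11, the largest falls were in Nudt12, which hydrolyses NADH, at -3.10 ± 0.088, Ccnb1ip1, at -2.12 ± 0.054, and Klf15, at -2.03 ± 0.13. The ubiquitin-conjugating enzyme gene Ube2d1 fell by 2.01, Zc4h2 by 2.02, Srgn by 2.00 and Cubn by 1.93. The probe sets of Pramel6, Pramel7, Myof and Cubn share probes with other transcripts.

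In total 4250 genes passed on day 3, 2425 higher and 1825 lower, with 101 up and 93 down at least 2-fold. Without knockout replicate 1 of day 3 the count was 2727, and with only the arrays of day 3 it was 2506. The controls of day 3 differed from those of days 1.5 and 6, as given further on, so an alternative chosen after seeing the data set the knockout cells of day 3 against the mean of the controls of days 1.5 and 6. The alternative counts any change of day 3 that both genotypes share as a knockout effect. It called 4637 genes, of which 39.3% were higher against 57.1% before, with 31 up and 139 down at least 2-fold. Of the genes just named, Anxa1 then turned to -1.16. Pramel6, Pramel7, Sycp1, Galc, Trmt10a, Egfl6 and Myof stayed higher, at 1.58, 1.14, 1.20, 2.20, 1.43, 0.77 and 1.01. Nudt12, Ccnb1ip1, Klf15, Ube2d1, Zc4h2, Srgn and Cubn stayed lower, at -2.98, -2.17, -1.72, -2.28, -2.20, -3.61 and -2.47.

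Of the 27 lists, 7 shifted on day 3 by camera, and 0 did so with an estimated correlation (5 at an unadjusted p under 0.05). Integrated stress response genes had 17 of 24 members lower and 0 higher (17 and 0 adjusted over the list alone), with Nupr1 at -1.01 ± 0.061, Vldlr (shared probes) at -0.93 ± 0.10 and Pck2 at -0.93 ± 0.076 (adjusted p = 1.9e-10, and adjusted p = 0.099 with an estimated correlation). Glycolysis and hypoxia genes, a list that took in Pigq, a gene of GPI anchor synthesis (shared probes), had 12 of 20 lower and 0 higher (14 and 0 adjusted over the list alone, and 12 of 19 lower without Pigq), led by Vegfa at -1.36 ± 0.057 and Bnip3 at -1.05 ± 0.091 (2.4e-07, and adjusted p = 0.099 with an estimated correlation). Lysosome and autophagy genes had 10 of 23 lower and 1 higher (12 and 1 adjusted over the list alone), such as Neu1, at -0.78 ± 0.091 (0.0011, and adjusted p = 0.29 with an estimated correlation). Germline genes had 9 of 14 higher and 1 lower (9 and 1 adjusted over the list alone). Slc25a31, an ADP/ATP carrier of germ cells, rose by 1.35 and Stk31 by 1.32, while Sycp3 fell by 0.90 (0.00059, and adjusted p = 0.15 with an estimated correlation). Primed epiblast genes had 7 of 13 higher (9 higher and 1 lower adjusted over the list alone), such as Foxd3 at 0.89 and Lef1 at 0.77 (0.0011, and adjusted p = 0.14 with an estimated correlation). Ribosome biogenesis genes had 14 of 34 higher (14 adjusted over the list alone), with the RNA polymerase I subunit Polr1a at 0.65 ± 0.054 (0.00052, and adjusted p = 0.14 with an estimated correlation). Core spliceosome genes had 7 of 31 higher (7 adjusted over the list alone, 0.017, and adjusted p = 0.29 with an estimated correlation).

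Set against the controls of days 1.5 and 6, stress response genes had 18 of 24 lower and 0 higher (camera adjusted p = 2.9e-10, and adjusted p = 0.10 with an estimated correlation). Germline genes had 7 of 14 higher and 0 lower (7.8e-05, and adjusted p = 0.12 with an estimated correlation), with Slc25a31 at 0.90, Stk31 at 0.49 and Sycp3 at 0.36. Glycolysis and hypoxia genes lost their call by camera, with 6 of 20 lower and 1 higher (median -0.067, camera adjusted p = 0.14), Vegfa stayed lower at -0.90 and Bnip3 was at 0.12. The other 4 lists lost theirs as well. Lysosome and autophagy genes had 9 of 23 higher and 2 lower (adjusted p = 0.11), with Neu1 at -0.24 (adjusted p = 0.058), and ribosome biogenesis genes 3 of 34 higher and 5 lower (1.0), with Polr1a at 0.40. Core spliceosome genes had 2 of 31 higher and 4 lower (0.41) and primed epiblast genes 4 of 13 higher and 1 lower (0.48), with Foxd3 at -0.039 and Lef1 at 0.012 (adjusted p of 0.74 and 0.92). Aminoacyl-tRNA synthetases, with 21 of 35 lower and 0 higher against 7 lower and 3 higher before (camera adjusted p = 0.56), shifted there (3.4e-06, and adjusted p = 0.12 with an estimated correlation). So did mitochondrial ribosome genes, with 17 of 76 lower and 1 higher against 5 lower and 21 higher before (0.0019, and adjusted p = 0.60 with an estimated correlation). Immediate early and heat shock genes had 7 of 14 lower and 1 higher, against 2 lower and 6 higher before. Fibroblast markers had 8 of 23 lower and 0 higher, against 1 lower and 4 higher before. By camera with an estimated correlation their adjusted p were 0.15 and 0.40 in that order. Extraembryonic endoderm genes had 12 of 20 lower and 1 higher (median -0.61, camera adjusted p = 3.4e-07, and adjusted p = 0.033 with an estimated correlation). Against the controls of day 3 they had 4 higher and 4 lower (median 0.067, camera adjusted p = 0.67). In controls of day 3 against day 1.5 the same list had 12 lower and 0 higher (median -0.58).

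By day 6, genes of the germline stood at the top of the rises. Slc25a31 went from an intensity of 61.58 ± 0.21 in controls to 580.8 ± 4.88 in knockout cells (SD, n = 2, log2 fold change 3.24 ± 0.088 SE). Sycp1 rose by 3.14 ± 0.12, Taf7l, a testis form of a general transcription factor subunit, by 2.57 ± 0.14 and Sycp2 by 2.52 ± 0.17. Galc, the secreted ligand gene Wnt5a, Usp17la and Caps2 completed the 8 largest, at 3.00, 2.85, 2.67 and 2.50. The largest falls after Thap11 were in Mmachc, at -3.66 ± 0.079, Iftap, at -3.63 ± 0.076, Zc4h2, at -3.21 ± 0.095, and Ube2d1, at -3.20 ± 0.088. Nudt12 fell by 3.19, the galactose mutarotase gene Galm by 2.93 and Ctu1, which takes part in tRNA thiolation, by 2.90. The other 3 probe sets of Iftap did not pass, and the probe set of Galm shares probes with other transcripts.

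On day 6, 5906 genes passed, 3129 higher and 2777 lower, and 266 rose and 187 fell at least 2-fold. Most changes were small, with a median size of 0.39 on the log2 scale among genes past the threshold. No left-out array moved this count by over 1.5 times. The 3 probe sets for 18S ribosomal RNA had a median of -0.43 in knockout against control cells of day 6.

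**Figure D3:**
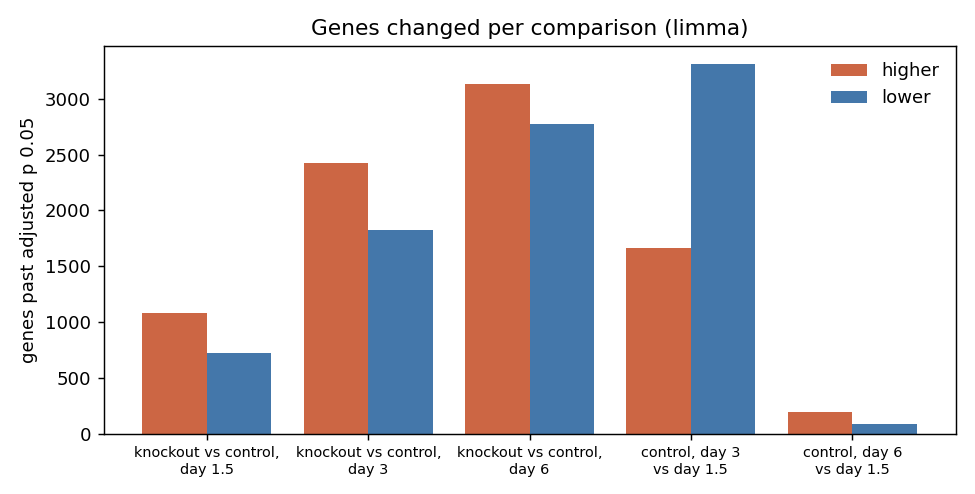
Number of genes past a limma adjusted p of 0.05 (y axis, of 18194 tested) that were higher (orange) or lower (blue) in each comparison (x axis). Knockout against control gave 1079 higher and 724 lower on day 1.5 and 3129 higher and 2777 lower on day 6, and controls of day 3 had 3307 lower against day 1.5.

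Of the 27 lists, 11 shifted on day 6, 5 upward and 6 downward, and 0 did so by camera with an estimated correlation (5 at an unadjusted p under 0.05). Germline genes had 11 of 14 members higher and 0 lower (12 and 1 adjusted over the list alone), with a median log2 fold change of 1.78 and Stag3, a meiotic cohesin subunit, at 2.48 ± 0.11 (camera adjusted p = 5.6e-10, and adjusted p = 0.068 with an estimated correlation). Of their brightest members that did not pass, Asz1 was at -0.15 and Tdrd1 at 0.36. Another probe set of Asz1 moved the other way past the threshold. Genes of the 2-cell-like state had 4 of 6 higher (6 adjusted over the list alone), with Usp17la at 2.67 and Tcstv1 at 1.90 (0.0017, and adjusted p = 0.15 with an estimated correlation). The other 9 members fixed for that list, among them Dux and 4 Zscan4 genes, were not measured. Tdpoz1, at 0.61, lost its call without control replicate 1 or knockout replicate 2 of day 6 (0.42 and 0.40), and Zfp352, at 0.24, without control replicate 2 or knockout replicate 1 (0.19 in both). Targets of p53 had 17 of 26 higher and 2 lower (17 and 2 adjusted over the list alone), among them Ddit4l at 1.15 ± 0.087, the DNA polymerase gene Polk at 0.85 ± 0.075 and Plk2 at 0.79 ± 0.052 (9.5e-06, and adjusted p = 0.12 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, was at 0.02 ± 0.081 on day 6 and at -0.43 on day 1.5 and -0.36 on day 3, calls that were lost when an array was left out. Cholesterol synthesis genes had 10 of 19 higher and 2 lower (10 and 2 adjusted over the list alone), such as Hsd17b7 (shared probes) at 0.71 and Insig1 at 0.65, while Ebp fell by 0.93 (0.0088, and adjusted p = 0.29 with an estimated correlation). Lysosome and autophagy genes had 11 of 23 higher and 2 lower (12 and 2 adjusted over the list alone), with Hexa at 0.80 ± 0.051 (0.0052, and adjusted p = 0.32 with an estimated correlation).

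**Figure D4:**
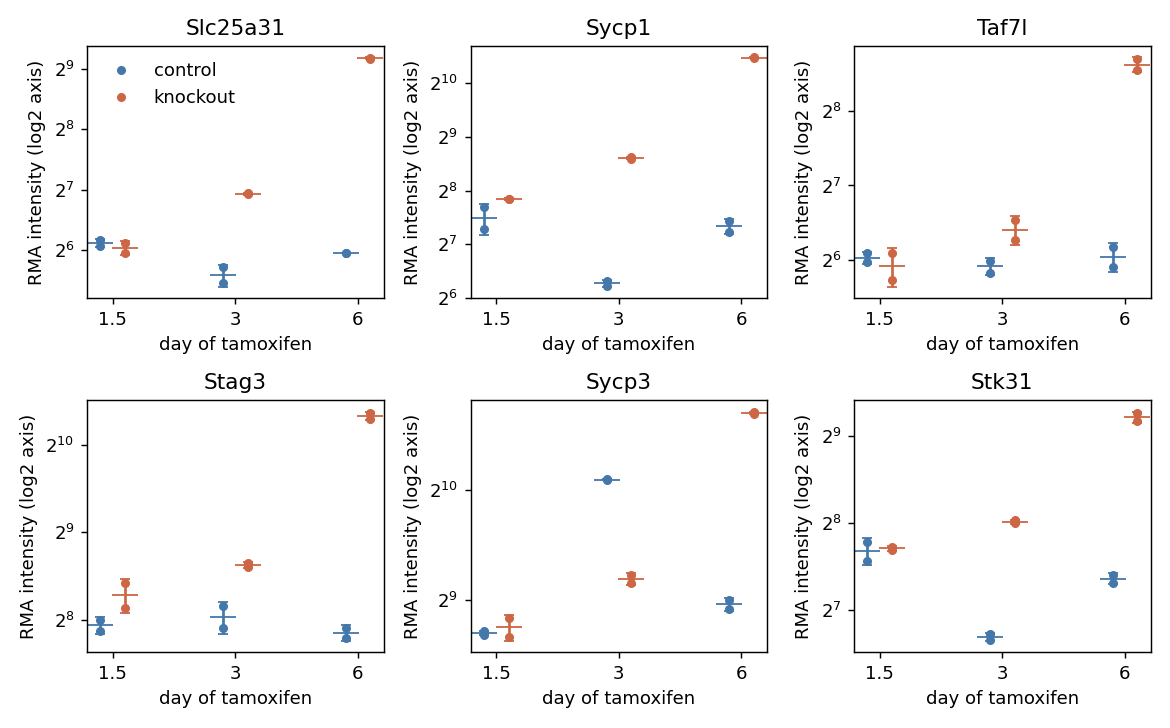
RMA intensity (y axis, log2 scale) of 6 germline genes by day of tamoxifen (x axis), with a point per array and the mean ± SD of 2 arrays in blue for control and orange for knockout. Slc25a31 in knockout cells went from 65.33 on day 1.5 to 580.8 on day 6, and Sycp3 was at 1094 in controls of day 3.

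Among the lists that shifted downward on day 6, mitochondrial ribosome genes had 34 of 76 lower and 2 higher (36 and 2 adjusted over the list alone). Mrpl34 fell by 2.06 ± 0.059, Mrpl24 by 1.81 ± 0.064 and Mrpl54 by 1.49 ± 0.060 (camera adjusted p = 3.9e-07, and adjusted p = 0.40 with an estimated correlation). The other probe set of Mrpl34 and that of Mrpl54 did not pass. Aminoacyl-tRNA synthetases, which charge tRNAs, had 17 of 35 lower and 2 higher (19 and 2 adjusted over the list alone), with the leucine enzyme gene Lars at -1.16 ± 0.052 (6e-04, and adjusted p = 0.25 with an estimated correlation). The list of translation initiation factors had 14 of 47 lower and 6 higher (14 and 6 adjusted over the list alone), with Eif1ax at -0.65 ± 0.048 (0.02, and adjusted p = 0.32 with an estimated correlation). It took in 4 kinases of eIF2 alpha, such as Eif2ak2 at 0.57, and the regulators Eif4ebp1 (shared probes), Eif4ebp2 and Eif4enif1. Without these 7 it had 13 of 40 lower and 4 higher (0.0081, and adjusted p = 0.21 with an estimated correlation). Ribosome biogenesis genes had 12 of 34 lower and 3 higher (12 and 3 adjusted over the list alone), with Lyar at -0.63 ± 0.050 (0.017, and adjusted p = 0.29 with an estimated correlation). Integrated stress response genes had 12 of 24 lower and 2 higher (12 and 3 adjusted over the list alone). Pck2 fell by 1.54 ± 0.076 and the mitochondrial serine enzyme gene Shmt2 (shared probes) by 1.26 ± 0.052, while Ddit3 rose by 0.87 ± 0.10 (9e-04, and adjusted p = 0.29 with an estimated correlation). In controls of day 6 against day 1.5 the stress response list had 12 of 24 higher and 0 lower (median 0.29). Its shift between knockout and control on day 6 thus also holds that rise of the controls. Glycolysis and hypoxia genes had 14 of 20 lower and 2 higher (14 and 2 adjusted over the list alone, and 13 of 19 lower without Pigq), with Vegfa at -1.05 ± 0.057, Tpi1 at -0.59 ± 0.053 and Pfkp at -0.58 ± 0.053 (0.00017, and adjusted p = 0.15 with an estimated correlation).

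Oxidative phosphorylation genes did not shift as a list on day 6 (17 of 81 lower, 9 higher, adjusted p = 0.43), yet Uqcr10, a complex III subunit, fell by 2.27 ± 0.067, from 4210 ± 74.5 to 871.5 ± 55.4 (SD, n = 2), and Cox7c (shared probes) fell by 2.03 ± 0.13. The median of the list was 0.0044 and its mean -0.073. Cytosolic ribosome genes had 3 of 49 lower and 1 higher. The cobalamin and one-carbon list that holds Mmachc had 7 of 19 lower and 4 higher (adjusted p = 0.30). The list of Ronin and HCF-1 cofactors, which also holds the related genes Thap1, Thap4 (shared probes) and Thap7, had 2 of 11 higher and 2 lower (adjusted p = 0.77). Hcfc1, whose product HCF-1 binds Ronin, was at -0.14 ± 0.074 (adjusted p = 0.18), and Ash2l rose by 0.59 ± 0.051. DNA replication genes had 6 of 31 higher and 7 lower, mitosis genes 4 of 21 higher and 3 lower, and core spliceosome genes 3 of 31 higher and 10 lower. Immediate early and heat shock genes had 4 of 14 higher and 5 lower (median 0.011, mean -0.14), and interferon response genes 1 of 17 higher and 3 lower, with Ifit2 at -2.23 ± 0.15.

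The lists of pluripotency, lineage and feeder markers did not shift by camera on day 6, but most had members that moved in both directions. Ground-state pluripotency genes had 8 of 24 higher and 4 lower (10 and 4 adjusted over the list alone, adjusted p = 0.11). Pou5f1, Nanog and Sox2, the core pluripotency factors, had log2 fold changes of 0.14 ± 0.047, -0.042 ± 0.052 and 0.087 ± 0.083, with adjusted p of 0.051, 0.61 and 0.49. None of the 3 passed on days 1.5 or 3 either, but on day 3 against the controls of days 1.5 and 6 Nanog was at 0.26 (adjusted p = 0.003). Nr5a2 and Tbx3 rose by 0.58 and 0.53, while Dppa3 and Klf4 fell by 0.62 and 0.44. Primed epiblast genes had 5 of 13 higher and 3 lower, trophectoderm and placenta genes 6 of 25 higher and 6 lower (median -0.03, mean 0.032), and extraembryonic endoderm genes 3 of 20 higher and 6 lower. Primitive streak and mesoderm genes had 1 of 16 higher, which was Tbx20 at 1.94 ± 0.15, and neuroectoderm genes 6 of 19 higher and 2 lower, with Sox1 at 1.62 ± 0.097. Markers of fibroblasts or feeder cells had 4 of 23 higher and 6 lower, with Ccn2 at 1.04 and Thy1 at -0.82. Adjusted p for these lists lay between 0.23 and 0.70.

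**Figure D5:**
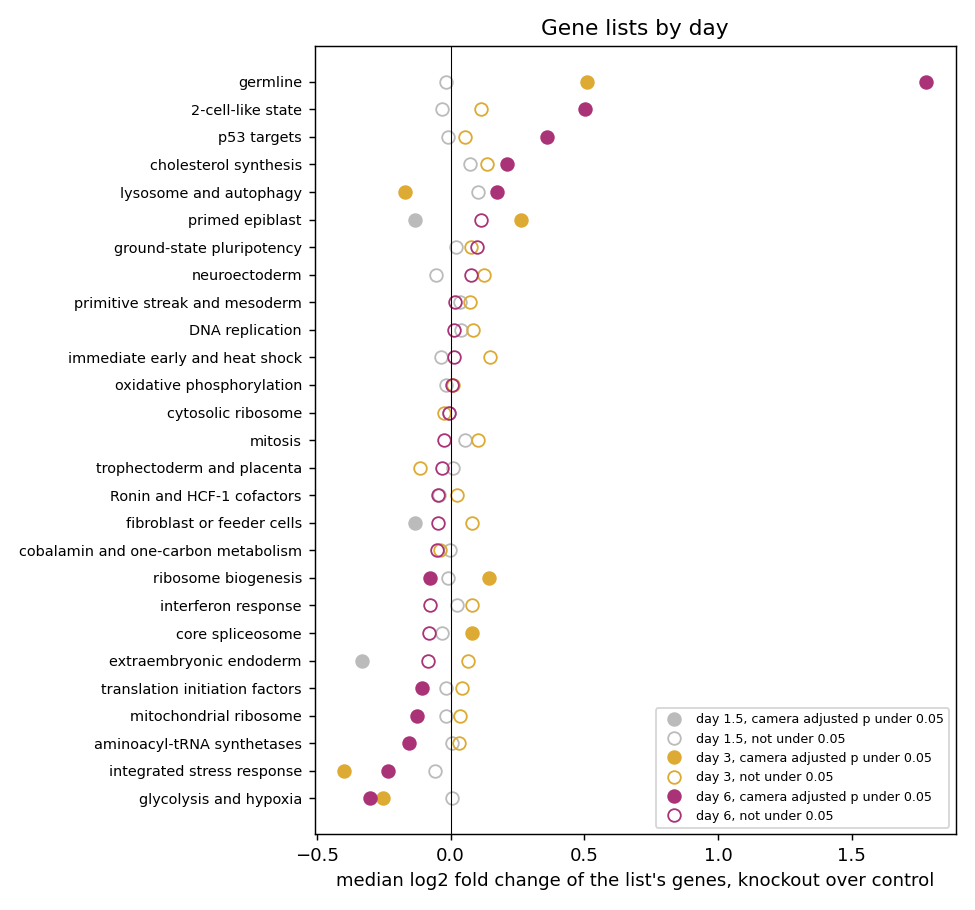
Median log2 fold change (x axis, knockout over control) of the genes of each of 27 lists (y axis) on days 1.5, 3 and 6, filled where the camera adjusted p with the preset correlation was under 0.05. Germline genes lie at -0.017, 0.51 and 1.78 on the 3 days.

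The change of the knockout effect between days was tested directly. From day 1.5 to day 6, Slc25a31, Wnt5a, Sycp1, Sycp2 and Taf7l had the largest increases, by 3.32 to 2.69 on the log2 scale, and Iftap, Mmachc, Cbr4, Thap11 and Galm the largest decreases, from -3.38 to -2.67. In that test 3516 genes passed, 1695 in the upward and 1821 in the downward direction, and 8 lists shifted. With an estimated correlation 1 of the 8, the germline list, kept its call (10 of 14 upward, median 1.71, adjusted p = 0.04). From day 3 to day 6, 2991 genes passed, with Sycp3 at 2.64 ± 0.092 and Iftap at -2.15 ± 0.11. Of 11 lists that shifted there, 3 passed with an estimated correlation, namely germline (10 of 14 upward, adjusted p = 0.044), p53 targets (12 of 26 upward, 0.049) and ribosome biogenesis (16 of 34 downward, 0.044). These values rest on the controls of day 3. With the effect of day 3 taken against the controls of days 1.5 and 6, chosen after seeing the data, 5050 genes passed, 3146 upward and 1904 downward, with Sycp3 at 1.38 and Iftap at -1.99. Germline genes then had 10 of 14 upward (adjusted p = 0.048 with an estimated correlation), p53 targets 15 of 26 upward (adjusted p = 0.12 with an estimated correlation) and ribosome biogenesis genes 7 of 34 downward (adjusted p = 0.22 with an estimated correlation). Extraembryonic endoderm genes had 12 of 20 upward there (adjusted p = 0.048 with an estimated correlation). With the controls of day 3 they had 1 upward and 2 downward (median -0.022, camera adjusted p = 0.6). From day 1.5 to day 3, 2723 genes passed, led by the cyclin gene Ccnd2 at 2.67 ± 0.088 and by Lrrc31 at -2.44 ± 0.23. Against the controls of days 1.5 and 6 the count was 3476, 1110 upward and 2366 downward, Ccnd2 was at 0.90 and Lrrc31 was at -0.37 (adjusted p = 0.18). Of 10 lists that shifted between those days, 0 passed by camera with an estimated correlation (8 at an unadjusted p under 0.05). For day 3 minus day 1.5 the count was 1810 genes without control replicate 1 of day 1.5, 1724 without knockout replicate 1 of day 1.5 and 1745 without knockout replicate 1 of day 3. For day 6 minus day 3 the counts were 1902 and 1983 without control replicates 1 and 2 of day 6, and 1905 and 1883 without knockout replicates 1 and 2 of day 6.

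Genes that changed on one day were also compared with those that changed on another. The days share no arrays but share each gene's estimate of spread and the same cell lines, so their calls are not independent. Days 3 and 6 shared 2337 genes changed in the same direction, 1313 higher and 1024 lower, where independent lists would share 417 and 279. A further 308 changed in opposite directions, and the fold changes of all genes correlated with r = 0.585 across genes, which are not independent replicates. Days 1.5 and 6 shared 555 higher and 363 lower (186 and 111 for independent lists), with 271 opposite and r = 0.306. Days 1.5 and 3 shared 437 higher and 262 lower (144 and 72.6), with 278 opposite and r = 0.224. On all 3 days 336 genes were higher and 215 lower. With days 3 and 6 each tested on their own arrays, 1497 genes were shared, and the number for independent lists was not computed there.

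The control cells give the background of time in culture with tamoxifen. On day 3 against day 1.5 the largest rises were in Lrrc31, at 2.17 ± 0.16, Pdlim4, at 1.96 ± 0.071, the water channel gene Aqp3, Pdzk1 and Sycp3, at 1.39 ± 0.065. The largest falls were in Glipr1, at -2.78 ± 0.18, the annexin genes Anxa1 and Anxa3, at -2.75 and -2.46, Spink1 and Cryab. In all 4966 genes passed, 1659 higher and 3307 lower, and 3156 without control replicate 1 of day 1.5. The share of higher genes was 33.4%, 22.5% after median centring and 44.8% after quantile normalization. Only the arrays of these 2 groups gave 2829 genes.

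In these controls 10 of 27 lists shifted, and 0 by camera with an estimated correlation (8 at an unadjusted p under 0.05). Lysosome and autophagy genes had 15 of 23 higher and 2 lower, glycolysis and hypoxia genes 10 of 20 higher and 2 lower and stress response genes 10 of 24 higher and 3 lower (16 and 2, 12 and 2, and 10 and 3 adjusted over the list alone). Cholesterol synthesis genes had 15 of 19 lower, extraembryonic endoderm genes 12 of 20 and ribosome biogenesis genes 16 of 34 (16, 12 and 21 adjusted over the list alone), with 0 higher in each. With an estimated correlation the adjusted p of these 6 lists were 0.098, 0.10, 0.50, 0.098, 0.061 and 0.098 in that order. Mitochondrial ribosome genes had 32 of 76 lower, core spliceosome genes 15 of 31 lower and 1 higher, immediate early and heat shock genes 8 of 14 lower and 1 higher and primed epiblast genes 6 of 13 lower and 1 higher. Their adjusted p with an estimated correlation were 0.50, 0.14, 0.098 and 0.16. The arrays of day 3 also differed in their spiked controls. The 18 hybridization control probe sets were lower on day 3 than on day 1.5 by a median of -0.58 in controls and -0.45 in knockout cells, and the 24 poly-A control probe sets were higher by 0.69 and 0.36. Between knockout and control on day 3 the same medians were 0.13 and -0.15. The 3 probe sets for 18S ribosomal RNA were higher on day 3 than on day 1.5 by a median of 1.38 in controls and 1.15 in knockout cells, and by 0.58 in controls of day 6. In knockout cells of day 6 against day 1.5 their median was -0.0023, and between knockout and control on day 1.5 it was 0.22. Between knockout and control on day 3 their median was -0.0085.

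In controls of day 6 against day 1.5, Efemp1 rose by 1.42 ± 0.14, and Csn3, Prss23 (shared probes), Sema3c and Pmp22 by 1.13 to 0.96. Ceacam20 fell by 1.21 ± 0.16. There were 285 genes past the threshold, 199 higher and 86 lower. This count depended on single arrays, with 28 and 40 genes without control replicates 1 and 2 of day 1.5, 51 and 18 without control replicates 1 and 2 of day 6, 184 without either knockout array of day 1.5 and 0 by limma with only the 4 arrays compared (2486 at an unadjusted p under 0.05). Of these named genes, Efemp1 alone kept its call without any 1 array. Of 27 lists 7 shifted, 5 upward and 2 downward, and 0 by camera with an estimated correlation (5 at an unadjusted p under 0.05). Stress response genes had 12 of 24 higher and 0 lower (19 and 0 adjusted over the list alone, median 0.29, camera adjusted p = 8.3e-18, and adjusted p = 0.055 with an estimated correlation). Trophectoderm genes had 5 of 25 higher, lysosome and autophagy genes 4 of 23, aminoacyl-tRNA synthetases 3 of 35 and fibroblast markers 3 of 23, the last with 1 lower (6, 5, 10 and 6 higher adjusted over the list alone), with adjusted p of 0.22 to 0.23 with an estimated correlation. Cholesterol synthesis genes shifted downward with a median of -0.11 (camera adjusted p = 2.5e-05, and adjusted p = 0.22 with an estimated correlation) and mitochondrial ribosome genes with a median of -0.031 (0.026, and adjusted p = 0.79 with an estimated correlation), with 0 single members past the limma threshold in either (1 and 0 lower adjusted over the list alone).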

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

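The differences between days against the controls of days 1.5 and 6, the list without Pigq, and the tests of gene order, of the ratio of day 6 to day 1.5, of the slope and spiked controls on day 3, and of the early germline and lineage medians were chosen after the results were seen. Groups of 2 arrays are too small for a test of single outlying arrays or of other splits of the samples.

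The knockout effect differed between days by a limma test of the difference for 2723 genes from day 1.5 to day 3, 2991 from day 3 to day 6 and 3516 from day 1.5 to day 6. From day 1.5 to day 3 the named differences were Ccnd2 2.67, Pramel6 2.62, Spink1 2.33, Acta2 2.27, Anxa1 2.22, Cbr4 -1.76, Thap11 -1.83, Ubd -1.97, Nudt12 -2.29 and Lrrc31 -2.44. From day 3 to day 6 they were Sycp3 2.64, Sycp2 2.40, Pdlim4 2.12, St6galnac3 2.11, Taf7l 2.08, Nxf3 -1.77, Gtf2h4 -1.81, Gbp2 -1.95, Mmachc -1.96 and Iftap -2.15. With the day 3 effect taken against the controls of days 1.5 and 6, Ccnd2 was at 0.90, Pramel6 at 1.12, Spink1 at 0.085 (adjusted p = 0.52), Acta2 at -0.18 (0.33), Anxa1 at -0.78 and Lrrc31 at -0.37 (0.18) for the earlier difference. For the later one Sycp3 was at 1.38, Pdlim4 at 0.28, Nxf3 at -0.69 and Gbp2 at -0.31 (adjusted p = 0.23), and the others moved by less than 1.5 times. The probe sets of Pramel6, Acta2, Gtf2h4 and Gbp2 share probes with other transcripts, as does that of Galm. From day 1.5 to day 6 they were Slc25a31 3.32, Wnt5a 2.79, Sycp1 2.78, Sycp2 2.775, Taf7l 2.69, Galm -2.665, Thap11 -2.875, Cbr4 -3.05, Mmachc -3.125 and Iftap -3.38. Among 9160 probe sets without a gene name, 89 changed on day 1.5, 426 on day 3 and 728 on day 6. Of 64 control probe sets of the array, 43 changed in control cells between days 1.5 and 3.

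Of 49 genes changed at least 2-fold on day 1.5, such as Ubd, Galc and Ccnb1ip1, 38 had changed in the same direction on day 6. A difference between the lines from before tamoxifen could place such genes near each other. In the data 3 pairs lay within 10 tested genes, against a median of 1 and a 95% range of 0 to 4 in random sets. The pairs were Glipr1 with Caps2 (-1.24 and 1.96), Galc with Ttc8 (2.58 and 1.29) and Ttc8 with Efcab11 (1.29 and 1.1). Galc, Ttc8 and Efcab11 lie near each other on chromosome 12, and all were higher. The bound first written would have counted this number of pairs against the explanation. That bound was wrong and was dropped after the value was seen, because line differences scattered over the genome give the same number. A growing response to the loss of Thap11 had a median ratio of day 6 to day 1.5 of 0.814 (95% interval 0.621 to 1.06), and a difference in single probe sets had a median ratio of the second to the first probe set of 0.307 (0.125 to 0.855, 26 genes). The 49 genes, Thap11 among them, were picked by the same day 1.5 change that divides both ratios. That choice pulls both ratios down, so neither decides. These explanations cannot be told apart, since no array precedes tamoxifen and CreERT2 goes with the knockout line.

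Controls of day 3 stood apart from those of days 1.5 and 6, with Anxa1 at -2.75 and Lrrc31 at 2.17 against day 1.5. An array batch that touched all arrays of day 3 alike would move knockout and control cells equally, but over all 18194 genes the slope of the knockout change on the control change was 0.318 (0.296 to 0.341, and 0.305 and 0.332 with single knockout replicates), which argues against it as the whole cause. The interval comes from resampling genes, which are not independent, and measures no spread between arrays or cultures. A batch could still be part of the cause, as the hybridization controls, which carry no cellular RNA, moved by -0.447 in knockout and -0.585 in control cells. A culture state with more glycolysis and hypoxia gene expression could also play a part, and the list median in controls was 0.177 (adjusted p = 0.10 with an estimated correlation; 0.185 and 0.094 without Pigq), short of the bound set beforehand.

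Germline genes had a median log2 fold change of 1.78 on day 6. A line difference present before tamoxifen would show on day 1.5, where their median was -0.0173, which argues against it. Differentiated cells would lower the ground-state pluripotency list and raise the 4 lineage lists. The pluripotency median was 0.0996, with 8 of 24 members higher and 4 lower, so that list did not fall as a whole. The 4 lineage list medians had a median of -0.0076. Of 80 lineage members 16 were higher, such as Tbx20 at 1.94 and Sox1 at 1.62, and 14 were lower. Both medians met the bound first written against this explanation. Since members moved both ways, these medians do not decide it, and differentiated cells in part of the cultures stay open. Lower mRNA of a known repressor could contribute and stays open, since of 12 such genes the lowest was Max at -0.723 (SE 0.097, adjusted p = 0.00045), between the bounds set beforehand. An effect of the loss of Thap11 itself also stays open, confounded with CreERT2.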

How the results depend on the processing

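The lists without members of another kind, the comparison of day 3 knockout cells with controls of days 1.5 and 6, the differences between days with that comparison, and the overlap of days 1.5 and 6, were chosen after seeing the data. Thap11 kept its direction and call under each alternative run, and without single arrays it ranged from -1.90 to -1.785 on day 1.5, -3.79 to -3.54 on day 3 and -4.76 to -4.68 on day 6. Where a group was left with 1 array, that array was assumed to vary like the other groups. Without single arrays the counts ranged from 714 to 1946 genes on day 1.5, 2727 to 4070 on day 3 and 4314 to 6031 on day 6. They ranged from 1724 to 2445 for day 3 minus day 1.5, 1883 to 2754 for day 6 minus day 3 and 2546 to 3705 for day 6 minus day 1.5. For controls of day 3 the range was 3156 to 4771, for controls of day 6 it was 18 to 259, for the overlap of days 3 and 6 it was 1689 to 2243, and 3 to 5, 6 to 8 and 11 to 11 lists shifted on days 1.5, 3 and 6. Of named genes past the threshold, 42 of 85 lost their call without some array on day 1.5, 20 of 116 on day 3, 13 of 115 on day 6 and 9 of 10 in controls of day 6. With only the arrays compared, which leaves fewer degrees of freedom, the counts were 455 on day 1.5, 2506 on day 3, 2829 for controls of day 3, 1497 for the overlap and 0 by limma for controls of day 6 (2486 genes at an unadjusted p under 0.05). With trend and robust eBayes they were 2756 genes and 9 lists on day 1.5 and 894 genes for controls of day 6, which also had 660 genes with the dimmest 40% left out and 187 with the mean of all probe sets. By camera with an estimated correlation, 1, 0 and 0 lists shifted on days 1.5, 3 and 6 (3, 5 and 5 at an unadjusted p under 0.05). Without Pigq and the 7 kinases and binding proteins, 3, 7 and 11 lists shifted. The replicate numbers do not pair the samples (correlations of replicate deviations within a day of -0.00375, -0.0573 and 0.0278, and between days of -0.0476 to 0.173, the highest between controls of days 1.5 and 3). With the replicate block the counts were 1657, 4111 and 5821 genes on the 3 days, 2543, 2810 and 3373 for the differences between days, 4808 and 210 for controls and 2263 for the overlap, with 3, 7 and 11 lists. The replicate block within day gave 863 genes on day 1.5, 1559 for day 3 minus day 1.5 and 1757 for day 6 minus day 3, and gives no value for the control time course. The overlap of days 1.5 and 6 was 918. With the mean of all probe sets 29 named values turned, 27 of them with no call on either side, on day 1.5 Ctsl -0.14, Fdft1 -0.0049, Ncl -0.036, Tfap2c -0.018, Rpl41 -0.13, Nars -0.0087, Zfp352 -0.11, Dnmt3b -0.027, Mrpl39 0.0067, Nodal 0.011, Mthfd1 0.056, Xaf1 0.013, on day 3 Dnmt3a -0.029, Lamc1 -0.048, Top2a -0.066, Map1lc3b -0.0073, Eif2s2 -0.0059, Hcfc1 -0.011, Slc2a1 0.024, Gapdh 0.0083, Hmgcs1 0.0052, Col5a1 0.022, Farsb 0.17 and on day 6 Lamc1 -0.26, Cdkn1a -0.11, Fdft1 -0.056, Hsp90aa1 -0.16, Atf4 0.032, Asz1 0.12. With quantile normalization 7 did, none with a call, on day 1.5 Rpl41 -0.0043, Dnmt3b -0.0053 and on day 3 Slc3a2 -0.0037, Mrpl15 -0.0048, Fdft1 -0.013, Snrpg -0.0091, Rpl41 0.0043, and with median centring 6, none with a call, on day 1.5 Mrpl39 0.011, Hspb1 0.0052, Pou5f1 0.00046, on day 3 Snrpg -0.0067 and on day 6 Mrpl51 -0.00024, Hsp90aa1 -0.00076. Without single arrays 37 named values, none with a call, lay on both sides of zero, on day 1.5 Kdr -0.093 to 0.19, Sycp3 -0.034 to 0.13, Hsp90aa1 -0.044 to 0.14, Npm1 -0.032 to 0.093, Cox6a1 -0.0055 to 0.047, Tfap2c -0.019 to 0.038, Usp17la -0.020 to 0.035, Rpl41 -0.0030 to 0.017, Nars -0.033 to 0.042, Zfp352 -0.015 to 0.018, Dnmt3b -0.013 to 0.013, Mrpl39 -0.034 to 0.029, Hspb1 -0.049 to 0.031, Gars -0.037 to 0.00086, Fn1 -0.053 to 0.013, Mthfd1 -0.10 to 0.014; on day 3 Neurod1 -0.037 to 0.22, Col4a1 -0.058 to 0.23, Pou3f1 -0.017 to 0.13, Asz1 -0.032 to 0.11, Slc3a2 -0.0028 to 0.081, Aars -0.039 to 0.10, Hcfc1 -0.070 to 0.12, Fdft1 -0.015 to 0.031, Snrpg -0.016 to 0.017, Hsp90aa1 -0.071 to 0.069, Slc2a1 -0.036 to 0.019, Rpl41 -0.055 to 0.032, Mthfd1 -0.071 to 0.021, Hmgcs1 -0.13 to 0.046, Farsb -0.11 to 0.010, Sox2 -0.14 to 0.012; on day 6 Uqcrb -0.015 to 0.10, Cdkn1a -0.00024 to 0.039, Fdft1 -0.0069 to 0.031, Rpl41 -0.0037 to 0.026, Hsp90aa1 -0.0063 to 0.022. Against controls of days 1.5 and 6, of 173 named values on day 3, 79 kept their direction and call, 23 lost and 10 gained the call, and 61 turned, 19 of which had no call on either side: Anxa1 -1.16, Tagln -1.24, Egr1 -0.15, Foxd3 -0.039, Gbx2 -0.58, Krt8 -1.36, Ccn2 -0.92, Cdh2 -0.44, Vim -0.46, Krt18 -1.38, Acta2 -1.78, Sox7 -0.56, Sparc -0.027, Aen -0.0049, Cd320 -0.053, Hspa1b -0.13, Ddx58 -0.42, Polr1b -0.13, Birc5 -0.041, Eif2ak1 -0.14, Ncam1 -0.033, Cars2 -0.11, Eomes -0.085, Eif6 -0.024, Rpl7l1 -0.013, Prpf31 -0.34, Sf3a3 -0.078, Prpf3 -0.0024, Idi1 -0.13, Dnmt3a -0.10, Irf9 -0.031, Atic -0.0086, Lamc1 -0.32, Ccng1 -0.036, Fos -1.76, Col4a1 -1.97, Wdr5 -0.0071, Ncl -0.024, Pou3f1 -0.11, Slc3a2 -0.16, Eif5a -0.040, Slc7a5 -0.15, Mrpl39 -0.055, Aars -0.019, Hcfc1 -0.065, Fdft1 -0.13, Snrpg -0.052, Hsp90aa1 0.050, Gapdh 0.042, Dppa5a 0.032, Nanog 0.26, Sox2 0.015, Ogt 0.032, Phlda2 0.072, Egln3 0.22, Tfap2c 0.15, Hexa 0.16, Dppa3 0.0062, Ddit4 0.068, Sycp3 0.36, Bnip3 0.12. The probe sets of Aars, Acta2, Eif5a, Farsb, Fdft1, Hmgcs1, Mrpl15, Rpl41, Snrpg, Tfap2c and Vim share probes with other transcripts, and other probe sets of Xaf1 and Ncl on day 1.5, Dnmt3a and Farsb on day 3 and Asz1 on day 6 moved the other way past the threshold. With the day 3 effect taken against those controls, 5050 genes differed for day 6 minus day 3, and for day 3 minus day 1.5 Acta2 turned to -0.18 and Anxa1 to -0.78. Comparisons with the controls of other days also hold any change of day 3 that both genotypes share. Except where the number of arrays changed, the cause was not tested. The number of arrays limits the precision, and signal over background was not analysed here.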

Other observations

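The test of the Zfp family was chosen after its result was seen. Several genes that fell on day 6 lie next to each other among the tested genes, and untested genes may lie between them. Mmachc, at -3.66, neighbours Ccdc163, at -1.15, and the complex III gene Uqcr10, at -2.27, neighbours Zmat5, at -1.43. Acad8 and Thyn1 were at -2.74 and -2.01, Vkorc1 and Bckdk at -1.03 and -2.38, Poglut2 and Bivm at -2.26 and -1.96, and Mcrip2 and Mettl26 at -1.19 and -2.09. Grb10 and LOC102631979 were at -2.27 and -1.75. The remaining pairs came from runs of neighbours whose middle gene was counted again. Gm3912, Gm45351 and Zik1 were at -1.34, -1.08 and -1.01, and Ttc9b, Map3k10 and Zfp607b at -1, -1.51 and -1.35. Zfp607b was already among the largest falls of day 1.5, so its fall is not particular to day 6. These pairs were named after their values were seen.

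The hypothesis tested was that neighbouring genes with shared promoters fell together. Of 187 genes that fell at least 2-fold on day 6, 186 were placed, and they formed 11 adjacent pairs, against a median of 2 and a 95% range of 0 to 5 in random sets matched on expression. Strand and promoter positions were not analysed here, so shared promoters were not told from other causes of nearness, and probes shared within a pair may add to the 11. A further hypothesis, that genes of the Zfp family fell together on day 6, had a family median of -0.000605 over 329 genes, with 75 lower and 75 higher (camera p = 0.48 with an estimated correlation), which argues against it.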
